A study of Danio rerio with 6 samples.

How the data were processed

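Messenger RNA of head cells sorted for a scarb2a reporter was sequenced from 3 scarb2a mutant and 3 wild type sibling pools. The method was a bulk form of MARS-seq, which tags the 3′ ends of polyadenylated transcripts, per the labels' protocols. The submitters' processing notes name the genome build danRer11; the aligner and the counter are not given in the sources used here. The authors deposited 1 table of 11218 genes in 6 libraries, whose name calls it normalized. Its values are a signal, in the deposited table, that behaves as gene counts divided by 1 factor per library: 99.997% of 67308 values were whole multiples of the value of 1 count (tolerance 0.0505), and 2 were not. The recovered totals were 1560238, 1599314 and 2086990 for wild type 1, 3 and 4, and 1838121, 1921206 and 2011118 for mutant 1, 2 and 3. Whether these are reads or molecules is not stated, so that intervals and floors cover counting error only. No gene had fewer than 6 counts in its highest library, so that the table holds no gene below that level. The table gives gene symbols; 89.0% of them were found in the RefSeq table of the assembly GRCz12tu, which was used only for older names and for which genes lie on 1 chromosome, since its build differs from danRer11. In all, 722 row names end in a number suffix; 290 pairs of such a row with the row of the same symbol were tested, and how the counting divided reads between them is not given in the sources used here.

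Libraries of 1 genotype differed by more than counting noise (chi-square per degree of freedom of 1.77 to 2.26 within genotypes, 6.47 to 9.41 between them), so none was counted as a duplicate. The groups, the tests, the 30 gene lists and the rule for named genes were fixed before the data were examined. The test was limma on log2(value + 1) with a mean-variance trend, genotype as the only term, for genes with a mean deposited value of at least 5; p values were adjusted by Benjamini and Hochberg's method and the threshold was 0.05. The values in the text are means ± SD of the deposited values over 3 libraries, and fold changes are the fitted log2 differences, mutant minus wild type. A gene at 0 in 1 group was compared with a floor of 3 counts over the group, and one with 1 to 3 counts by the ratio of summed counts with an exact binomial 95% interval. Gene lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with the correlation estimated per list, and with fry; p values were adjusted over 30 lists. Of 1696 list entries, 1047 matched a row by symbol and 46 by an older name.

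Genes were named by a fixed rule: scarb2a with its paralogues and the glucocerebrosidase gene; in each direction the 12 largest changes among described symbols that passed and whose groups did not overlap; up to 4 members with the smallest p of each list that passed or held a called gene; and up to 2 of the others. Genes named outside it are said to be chosen after their values were seen; cspg5a, tbr1b and cahz lie outside it too, and are named because each passed in the direction against that of its list. scarb2a fell under the filter on low values, so its difference was tested by exact permutation and, without the filter, by limma. The alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 20, median ratio, equal total and quantile scaling, limma without a trend and with sample weights, edgeR and DESeq2 on the recovered counts, a replicate block, each library left out in turn, other thresholds, and other list tests. After the data had been seen, 1 alternative was added, and 6 lists put together by hand from genes seen to move were tested once and left out, because they had been selected on their outcome; families of genes that share the start of their symbol were used in their place.

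The procedure was tested on simulated data with the real means, size factors and dispersions of this comparison, with 9639 genes tested, of which 50, 46, 47 and 45 were changed 1.5-fold, 2-fold, 4-fold and 8-fold. It recovered 40.0% of genes changed 1.5-fold, 60.9% of those changed 2-fold, 89.4% of those changed 4-fold and 100% of those changed 8-fold. There were 11 false calls among 146, and no gene list was called. Genes were drawn independently and those changed were picked at random, so the simulation could not examine the list tests. It changed 200 genes, against 1873 called in the data, so the recovery in the data may differ. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.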

Results

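Gene expression was measured in cells sorted for a scarb2a reporter from zebrafish (Danio rerio) heads at 48 hours post fertilization, in scarb2a mutants and their wild type siblings. scarb2a encodes a zebrafish homologue of LIMP-2, a lysosomal membrane protein that carries glucocerebrosidase to lysosomes. Each library came from 5000 live cells, sorted for a red fluorescent reporter driven by scarb2a regulatory sequence, from a pool of 50 heads. There were 3 libraries per genotype, which the labels call biological replicates: wild type 1, 3 and 4, and mutant 1, 2 and 3. The deposited table listed normalized counts for 11218 genes. The counts behind it came to between 1560238 and 2086990 per library. The series title places the question in radial glia progenitors, brain vessels and the blood-brain barrier. Markers of other cell types that the reporter gate could hold were therefore examined beside the pathways.

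The mutated gene itself was close to the detection limit and gave no check of the genotype labels or of the sort. scarb2a was listed at 2.43 ± 0.971 normalized counts in wild type and 3.80 ± 2.52 in mutants (SD, n = 3), from 7 and 12 counts in total. The mutant level was higher by 0.34 on the log2(value + 1) scale, which did not differ from 0 (exact permutation test, two-sided, p = 0.7, where 0.1 is the smallest p that 3 against 3 libraries allow). Without the filter on low values the limma adjusted p was 0.77. A mutant allele can still give a transcript, and a tag from the 3′ end lies outside many lesions. The paralogue scarb2c, listed under an older clone name, had 4.5 ± 2.74 normalized counts in wild type and 4.17 ± 3.76 in mutants (SD, n = 3). The glucocerebrosidase gene gba had 4.53 ± 2.02 and 4.2 ± 1.91 (SD, n = 3). No difference in these genes was detectable at this depth. The values lie near the detection limit, and scarb2b was not analysed here.

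The comparison asked how the sorted cells of scarb2a mutants differ from those of their siblings. Genes of cholesterol synthesis, extracellular matrix, mesenchyme, skin, heat shock and the cell cycle were higher in the mutant. Lens, retina and neuronal genes were lower, and none of the lysosomal, endosomal and autophagy lists passed a test for a common direction. Of 30 gene lists 15 passed limma's camera with a preset correlation, 12 higher and 3 lower. With a correlation estimated per list none passed, with 10 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0532. limma's fry called 13. For the Wnt and angiogenic lists the estimated correlations, -0.00368 and -0.0264, lay below the preset 0.01. Their unadjusted camera p still went from 4.11e-05 to 0.00887 and from 1.96e-04 to 0.0130. Correlated members therefore do not explain why these lists lost their calls. The other 9 ways to part the 6 libraries into 3 and 3 gave 0 genes and 8 to 16 lists past the same thresholds. Each of those splits mixes the genotypes, so the genotype difference widens the spread within its groups. The 0 genes were thus close to fixed in advance, and neither count is a rate of false calls.

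Of 9647 genes with a mean of at least 5, 1873 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment: 1053 were higher and 820 lower in the mutant. The first principal component held 54.3% of the variance and parted the genotypes. The 3 mutant values lay on one side of all 3 wild type values for 34.6% of the genes tested, against 10% by chance. A change of at least 1 on the log2 scale was seen for 431 of the higher and 266 of the lower genes. The balance of higher and lower calls depended on scaling. With every library scaled to the same total, the median over all genes shifted by -0.11 on the log2 scale, and 795 genes were higher and 1306 lower. No gene called under both scalings changed direction, but so small a shift could hardly reverse a gene called in both. Ribosomal protein genes took 32.3 to 34.9% of the counts in the wild type libraries and 36.2 to 37.8% in the mutant ones. The fold changes below are on the log2(value + 1) scale, which understates changes of low genes.

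Genes of cholesterol synthesis rose together in the mutant. cyp51, the lanosterol demethylase, rose from 9.97 ± 5.41 to 110.5 ± 6.16 normalized counts (SD, n = 3), a ratio of 11.1 and a log2 fold change of 3.45 ± 0.256 (SE; limma adjusted p = 1.05e-08). mvda, which makes isopentenyl diphosphate, rose from 11.6 ± 3.2 to 59.9 ± 9.88, and hmgcs1, the HMG-CoA synthase, from 28.8 ± 6.90 to 99.1 ± 7.05. srebf2, the transcription factor that drives sterol genes, rose from 111.2 ± 6.15 to 270.7 ± 11.6 (adjusted p = 2.40e-08). Of 21 members tested, 16 rose, none fell and 5 did not pass; 18 rose when adjusted over the list alone. The list's median log2 fold change was 1.28, and limma's camera gave an adjusted p of 5.08e-14 over 30 lists; the adjusted p was 0.0532 with an estimated correlation. Mesenchymal, matrix and skin markers, 75 genes together, rose in the same libraries with a median of 1.12. Cholesterol transport and efflux genes did not move as a list: of 24 tested, flot2a, flot1b and ch25h rose and the exporter gene abca1a fell (2 and 1 adjusted over the list alone), with a camera adjusted p of 0.553 and a median that turned to -0.10 with equal totals. The abca1a change of -1.21 was -0.76 without mutant replicate 1 (adjusted p = 0.103) and lost its call without wild type replicate 1 or 4 (0.0866 and 0.0550), and ch25h lost its call without wild type replicate 1 or 4 or mutant replicate 2 or 3 (adjusted p up to 0.210).

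**Figure D1:**
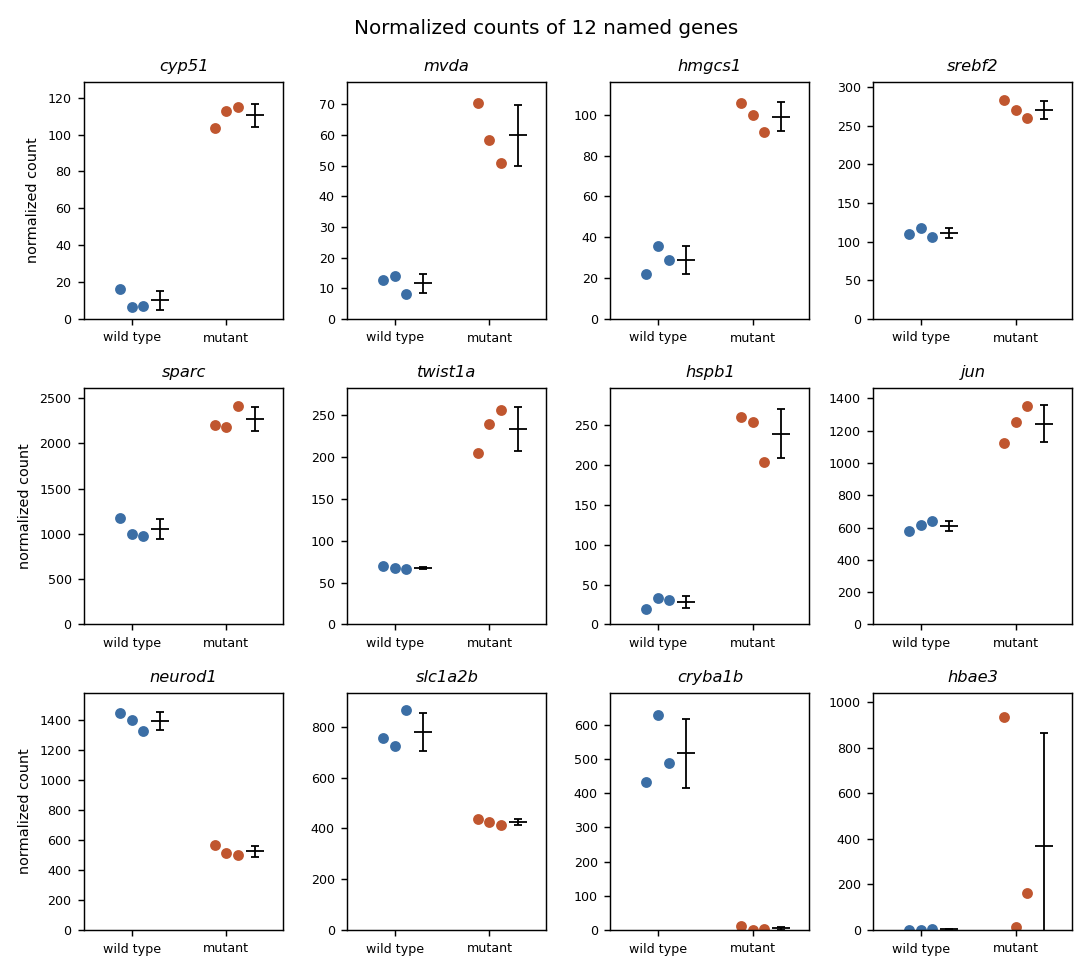
Normalized counts (y axis, linear, from 0) of 12 genes in the 3 wild type and 3 mutant libraries; each point is a library and the black marks are the mean ± SD. Sterol genes such as cyp51 lie apart between genotypes (6.5 to 16.2 against 103.5 or more), while hbae3 is high mainly in mutant replicate 1, where it reaches 935.6.

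Extracellular matrix, mesenchyme and skin markers were higher in the mutant. Of 36 matrix and basement membrane genes tested, 26 rose and 1 fell (29 and 1 adjusted over the list alone), with a median of 1.1. matn4, a cartilage matrilin, rose from 238.8 ± 33.8 to 721.3 ± 62.2 (SD, n = 3). The collagen genes col1a1b and col12a1a rose by 1.15 and 1.43, and postnb, encoding periostin, by 1.18. The cspg5a change was -0.77. Of 15 mural cell and fibroblast markers 11 rose and none fell (12 and 1 over the list alone). twist1a, a transcription factor of mesenchyme, rose from 67.7 ± 1.40 to 233.4 ± 26.0, and foxc1a and foxc1b rose by 1.66 each. Of 30 markers of epidermis and neural crest derivatives 20 rose and 2 fell (22 and 2 over the list alone). The melanocyte genes pmela and tyrp1b rose by 1.6 and 1.27, the chondrogenic gene lect1 rose by 1.48, and tfap2b changed by -0.86. Camera adjusted p values were 4.14e-17, 6.86e-11 and 3.80e-12 for the matrix, mural and epidermal lists, and an adjusted p of 0.0532 for each with an estimated correlation. Another list held 6 of the 36, 6 of the 15 and 4 of the 30 genes.

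Lens, retina and neuronal transcripts were lower in the mutant. Of 39 lens and retina markers 31 fell and none rose (33 fell adjusted over the list alone), with a median of -1.73. Lens genes fell most. They belong to families of near-identical genes, so the values of single members are uncertain. cryba1b, a lens crystallin, was at 516.4 ± 101 normalized counts in wild type and 4.03 ± 5.50 in mutants (SD, n = 3), and crybb1 at 471.2 ± 116 and 3.43 ± 4.33. The summed counts of crygn2 were 66.0 times higher in wild type (95% exact interval 45.2 to 100.4, counting error only). With only 3 counts in the mutants, cryba2a had a ratio of 106.2 (36.0 to 517.6). Without mutant replicate 1 these ratios were 101.8 and 218.5, and that of cryba2a was 68.1 without mutant replicate 3. Over 31 lens genes taken by name, the share of all counts was 0.198 to 0.300% in the wild type libraries and 0.00302 to 0.00675% in the mutant ones (95% exact intervals from 0.191 to 0.308% and from 0.00229 to 0.00804%). Of the 22 retinal members without those lens genes, 14 fell, with a median of -1.09. Of 64 neuronal markers 26 fell and only tbr1b rose (28 and 2 over the list alone). The proneural gene neurod1 fell from 1391.6 ± 62.1 to 524.3 ± 35.7, neurod6b changed by -1.602, neurod4, which shares its symbol with another row and is uncertain, by -0.97 and the synaptic gene snap25b by -1.02. Camera adjusted p values were 9.61e-34 for lens and retina and 7.82e-11 for neurons, and an adjusted p of 0.0538 for each with an estimated correlation.

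Radial glia markers moved in both directions. Of 41 tested, 8 rose and 15 fell (9 and 17 adjusted over the list alone), with a median of -0.18 and a camera adjusted p of 0.0518 (0.322 with an estimated correlation). With equal totals the median was -0.29 and the adjusted p 0.0298. The list passed without wild type replicate 3 (0.0326), mutant replicate 1 (0.0390) or mutant replicate 2 (0.0274), and in 11 of 21 alternatives. The glial glutamate transporter gene slc1a2b fell from 781.1 ± 74.5 to 425.1 ± 12.1 (SD, n = 3), and otx2 and mdkb changed by -0.83 and -0.70. sparc, which encodes a matrix glycoprotein that mesenchyme also makes, rose from 1051 ± 111 to 2266 ± 129. Chosen after their values were seen, gfap, encoding the glial filament protein, changed by -0.98 and fabp7a, encoding a brain lipid binding protein, by -1.09, while slc1a3a, another glutamate transporter gene, rose by 0.81. Of 8 oligodendrocyte lineage markers, olig2 and plp1a fell, by 0.92 and 1.06 on the log2 scale, as they did adjusted over the list alone, and the list did not pass (camera adjusted p = 0.159).

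Heat shock and immediate early genes, which cell dissociation is known to induce, were higher in the mutant libraries. Of 44 tested, 24 rose and 2 fell (29 and 2 adjusted over the list alone), with a median of 0.65. hspb1, a small heat shock protein gene, rose from 27.9 ± 7.35 to 239.5 ± 30.9 (SD, n = 3), hsp70.3 by 3.34, jun by 1.02 and ier2a by 0.90. Of 31 genes of endoplasmic reticulum stress 9 rose and 1 fell (10 and 1 over the list alone), among the risers ddit3 by 0.85, atf3 by 1.02 and the spliced stress factor gene xbp1 by 0.41. Camera adjusted p values were 3.77e-16 and 5.52e-04, and adjusted p values of 0.0600 and 0.134 with an estimated correlation. Of 24 genes of p53 and apoptosis, 5 rose, sesn2 by 1.64, and 1 fell (9 and 1 over the list alone), and the list did not pass (camera adjusted p = 0.113), except without wild type replicate 4 (median 0.43, 0.0380).

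Proliferation and ribosomal protein genes shifted by small steps. Of 62 proliferation genes 22 rose and none fell (24 over the list alone): pcna, the replication clamp, rose from 1293 ± 36.2 to 2064 ± 93.1 (SD, n = 3), mcm4 by 0.94, mcm2 by 0.88 and cdca7b by 1.14. Of 76 ribosomal protein genes 46 rose and 1 fell (59 and 3 over the list alone), with a median of 0.26, or 0.15 with equal totals and 0.07 with quantile normalization, and fry did not call the list (adjusted p = 0.0620). rpl7 rose by 0.40 and rpl4 by 0.38. Camera adjusted p values were 1.12e-07 and 9.35e-16, and adjusted p values of 0.182 and 0.322 with an estimated correlation. Of 65 genes of oxidative phosphorylation 1 rose and 9 fell (0 and 2 over the list alone), with a median of -0.09 and a camera adjusted p of 0.0115 (0.536 with an estimated correlation). That call was lost without wild type replicate 1 (median -0.05, 0.0641) or mutant replicate 3 (median -0.05, 0.0852), and in edgeR (0.0689), limma without a trend and fry (0.170). With equal totals the median was -0.20 (8.39e-06). Of 30 genes of glycolysis and hypoxia 7 rose and 5 fell, among them igfbp1a, up by 1.56, and ndrg1a at -1.35 (7 and 6 over the list alone), and the list did not pass (camera adjusted p = 0.551; the median of 0.03 was -0.09 with equal totals).

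The endolysosomal lists did not pass a test for a common direction. fry's test for changes in either direction gave them adjusted p values from 6.16e-05 (V-ATPase) to 0.0269 (lysosomal membrane). It compares a list with no other genes, and the Notch list passed it too (8.61e-05), so that result is not particular to these lists. None of 22 lysosomal membrane genes passed, with a median of 0.00499 and a camera adjusted p of 0.994; 2 of them were past an unadjusted p of 0.05, and the sign of the median changed between settings. Among them slc11a2, an iron transporter gene, passed without wild type replicate 3 (0.51, adjusted p = 0.0437). Of 39 lysosomal hydrolase genes 4 rose and none fell (2 over the list alone), with a camera adjusted p of 0.159. These were ctsk, which encodes cathepsin K and rose from 36.5 ± 9.85 to 91.9 ± 8.53 (SD, n = 3), ctsz at 1.36, and ctss2.1 and scpep1, whose calls were lost when 1 library was left out (ctss2.1 without wild type replicate 3 or 4 or mutant replicate 2 or 3, adjusted p up to 0.258, with 0.54 on the log2 scale without mutant replicate 3; scpep1 without any 1 library except wild type replicate 1, up to 0.153). The saposin precursor gene psap, chosen after its values were seen, had 298.7 ± 23.7 and 303.0 ± 18.2. Of 18 genes of the V-ATPase, the proton pump that acidifies lysosomes, 6 fell and 1 rose (7 and 2 over the list alone; camera adjusted p = 0.0808). Their median was -0.21, or -0.31 with equal totals, -0.10 without wild type replicate 3 and -0.07 without mutant replicate 1. They took 0.200 to 0.214% of the counts in the wild type libraries and 0.157 to 0.170% in the mutant ones (95% exact intervals from 0.193 to 0.220% and from 0.151 to 0.175%). atp6v0cb changed by -0.53 and atp6v1e1b by -0.40. The riser, atp6v1g1, went from 99.6 ± 6.39 to 193.5 ± 8.55, while another row of the same symbol, atp6v1g1_1, fell from 210.3 ± 4.58 to 1.97 ± 0.153. The sum of both rows was 309.9 in wild type and 195.5 in mutants, -0.66 on the log2 scale. The rise of the single row is thus uncertain as a change of the gene. The V-ATPase list held atp6v1g1 and not atp6v1g1_1, so its 1 riser, its median, its share and its test all use the split gene. Whether the list passes with both rows summed was not tested. Of 34 autophagy and mTOR genes only sesn2 and sqstm1 rose (camera adjusted p = 0.705), and of 14 sphingolipid genes only sgms1 and degs1 (0.211), with 2 in each when adjusted over the list alone. The median, the mean and the test differ in sign for the autophagy and lysosomal membrane lists. Of 61 endosomal trafficking genes rab11bb and ap2a1 fell and snx1a rose, and none passed when adjusted over the list alone (camera adjusted p = 0.532). Each of these calls was lost without wild type replicate 3 (adjusted p of 0.0671, 0.0526 and 0.0685) and without mutant replicate 3 (0.0700, 0.0906 and 0.138), and those of ap2a1 and snx1a also without wild type replicate 1 or 4 or mutant replicate 2 (up to 0.147).

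In the lists of angiogenic signals, the Wnt pathway and endothelial markers more genes rose than fell, and the mural cell and fibroblast markers were higher in the same libraries. Of 32 angiogenic genes 12 rose and 2 fell (13 and 2 over the list alone), with a median of 0.49, or 0.32 without mutant replicate 1. mmp2, a matrix metalloprotease gene, rose from 11.4 ± 1.97 to 39.4 ± 6.25 (SD, n = 3), angptl4 by 0.81, and thbs1b, which encodes an angiogenesis inhibitor, by 1.32. vegfaa, chosen after its values were seen, rose from 3.77 ± 1.72 to 13.2 ± 4.304 (adjusted p = 0.0141), a call lost without mutant replicate 1 or 2 (0.0713 and 0.0784). Of 36 Wnt pathway genes 16 rose and 2 fell (19 and 3 over the list alone). These include the secreted inhibitor gene wif1 at 1.23, reck, a cofactor of Wnt7 signalling in brain vessels, at 1.31, and the receptor genes fzd2 at 1.24 and fzd7b at 1.19. Of 18 endothelial markers 6 rose and 2 fell (8 and 2 over the list alone): fli1a rose by 1.81, the junction gene cldn5b changed by -0.73, pecam1 rose by 1.56, or 0.94 without wild type replicate 1, and etv2 rose by 1.47, a call lost without mutant replicate 3 (0.0693). Camera adjusted p values were 4.90e-04, 1.23e-04 and 0.00963 for the angiogenic, Wnt and endothelial lists, and adjusted p values of 0.0538, 0.0532 and 0.175 with an estimated correlation. With only genes of a mean of at least 20, the endothelial list did not pass (median 0.31). Of 37 Notch pathway genes 4 rose and 4 fell (4 and 4 over the list alone; camera adjusted p = 0.994; the median and the mean differ in sign), with the ligand gene dlb up by 0.55 and notch2 up by 1.59. her4.3, a Notch target with near-identical copies and thus uncertain, fell from 1001 ± 139 to 804.0 ± 48.5 (SD, n = 3), a call lost without wild type replicate 3 or 4 or mutant replicate 2 or 3 (adjusted p up to 0.127).

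**Figure D2:**
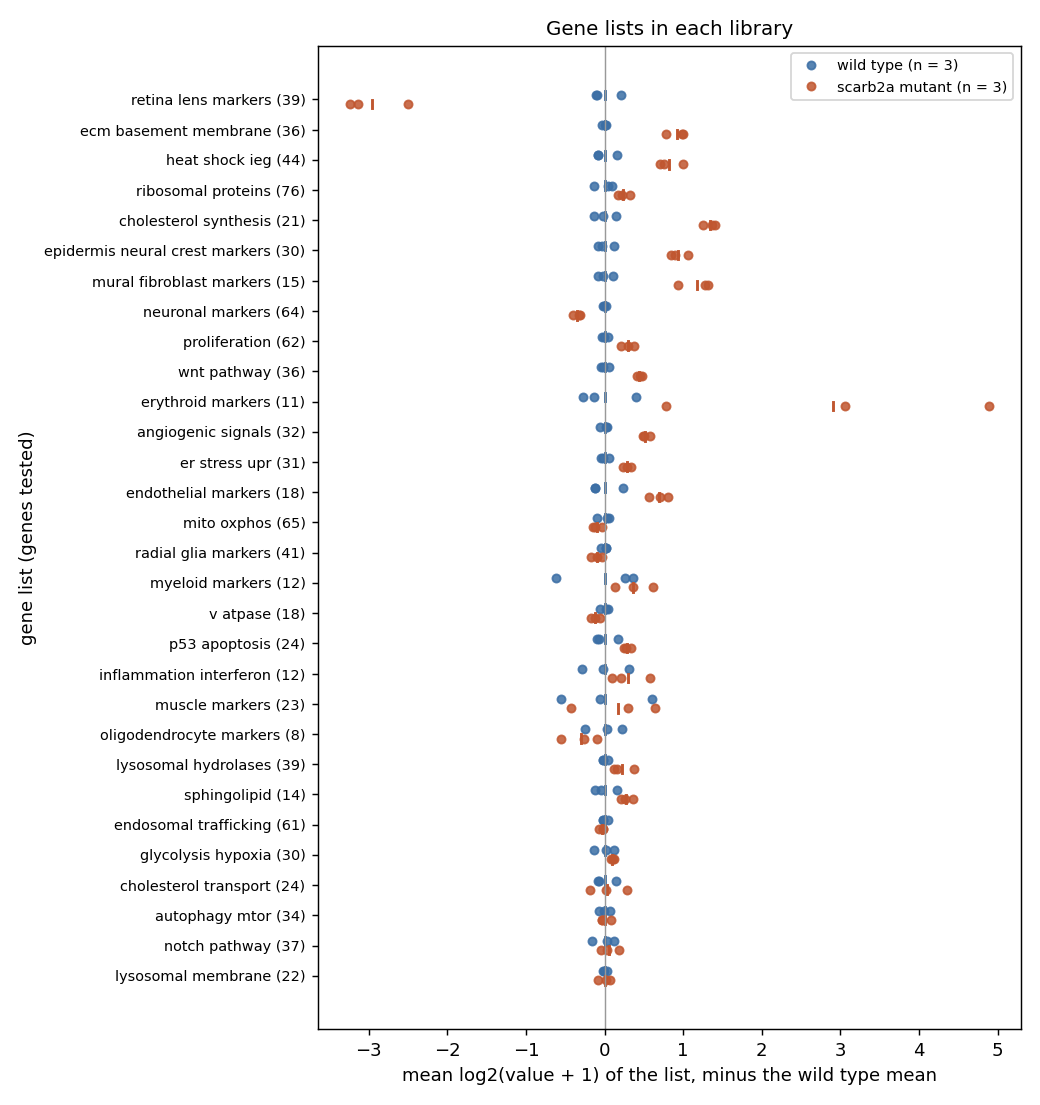
Mean log2(value + 1) of each gene list per library, minus the wild type mean (x axis), for 30 lists in order of their camera p (y axis, genes tested in brackets); points are libraries and short bars are group means. The lens and retina list lies below 0 in all 3 mutants, at -2.50, -3.24 and -3.13, and the erythroid list is spread from 0.79 to 4.89 among them.

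Red blood cell transcripts were present in the mutant libraries in very unequal amounts. Of 11 erythroid genes 7, all globin genes, rose and cahz fell (8 and 1 over the list alone), with a camera adjusted p of 2.09e-04 (adjusted p = 0.322 with an estimated correlation); fry did not call the list (adjusted p = 0.103). The median was 3.72, or 4.63 with genes at 0 in a group set to their bound, and 1.86 without mutant replicate 1. It depends on how genes at 0 are fitted, with 6.85 in edgeR, a higher value still in DESeq2, and a lower one with a pseudocount of 5. Embryonic globins took 0.120% of the counts in mutant 1 (95% exact interval 0.115 to 0.125), 0.0194% in mutant 3 and 0.00104% in mutant 2. In wild type 4 the share was 0.000479%, and none of the counts of wild type 1 and 3 came from them, which allows shares up to 0.000236 and 0.000231% by the exact interval. Globin genes are near-identical to each other, so single members are uncertain. hbae3 had 935.6 normalized counts in mutant 1 and 11.9 in mutant 2. hbae1.3 and hbbe1.2 were at 0 in all wild type libraries and at least 94.97-fold and 46.3-fold higher in the mutants, against a floor of 3 counts over the group. In mutants 1, 2 and 3 hbae1.3 had 249.4, 1.0 and 42.6 normalized counts, and hbbe1.2 had 105.6, 3.0 and 32.6. The bounds were 22.99 and 18.7 without mutant 1, and 56.0 and 27.3 without wild type 4, the deepest wild type library. Of 12 myeloid markers mfap4 and ctss2.1 rose (camera adjusted p = 0.0626), of 12 inflammatory genes ptgs2a and stat3 (0.128), and of 23 muscle markers eno3 and nme2b.2 (0.159). Adjusted over the list alone, 4 myeloid genes rose and 1 fell, 5 inflammatory genes rose and 1 fell, and 2 muscle genes rose. With an estimated correlation the camera adjusted p values of the myeloid, inflammatory and muscle lists were 0.419, 0.322 and 0.707. The calls that follow use the preset correlation. The myeloid list passed without wild type replicate 3 (0.00709) or mutant replicate 1 (0.0328) and with equal totals (0.0271), the inflammatory list without wild type replicate 4 (0.0183) and with no filter on low values, and the muscle list without wild type replicate 4 (0.00146) or mutant replicate 1 (0.00763), where its median of 0.16 was 0.64 and 0.54; it was 0.05 with equal totals, and below 0 without wild type replicate 1 or mutant replicate 3. The stat3 call was lost without wild type replicate 1 or 4 or mutant replicate 1 or 2 (adjusted p up to 0.176).

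Among the largest rises outside these lists, arf4b, a small GTPase gene, had 1 count in the wild type libraries and 61 in the mutants, a ratio of 60.1 (95% exact interval 10.4 to 2414, counting error only). cart4, which encodes a neuropeptide, had 2 and 60 counts (29.6; 7.84 to 249.8), and mlf1 had 3 and 49 (16.1; 5.20 to 80.8). The cart4 ratio was 16.1 without mutant replicate 3 and 17.4 without wild type replicate 4, that of mlf1 was 34.5 without wild type replicate 1, and arf4b was at least 11.8-fold higher without wild type replicate 4, where its 1 wild type count lies. The muscle regulator gene myf5 rose from 1.80 ± 3.12 to 15.13 ± 10.5 normalized counts (SD, n = 3; limma adjusted p = 0.00398), a call lost in limma without a trend and in DESeq2. All 5 wild type counts of myf5 lay in wild type replicate 3, and its ratio of summed counts of 9.46 was 5.53 without mutant replicate 3 and 5.58 without wild type replicate 4.

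**Figure D3:**
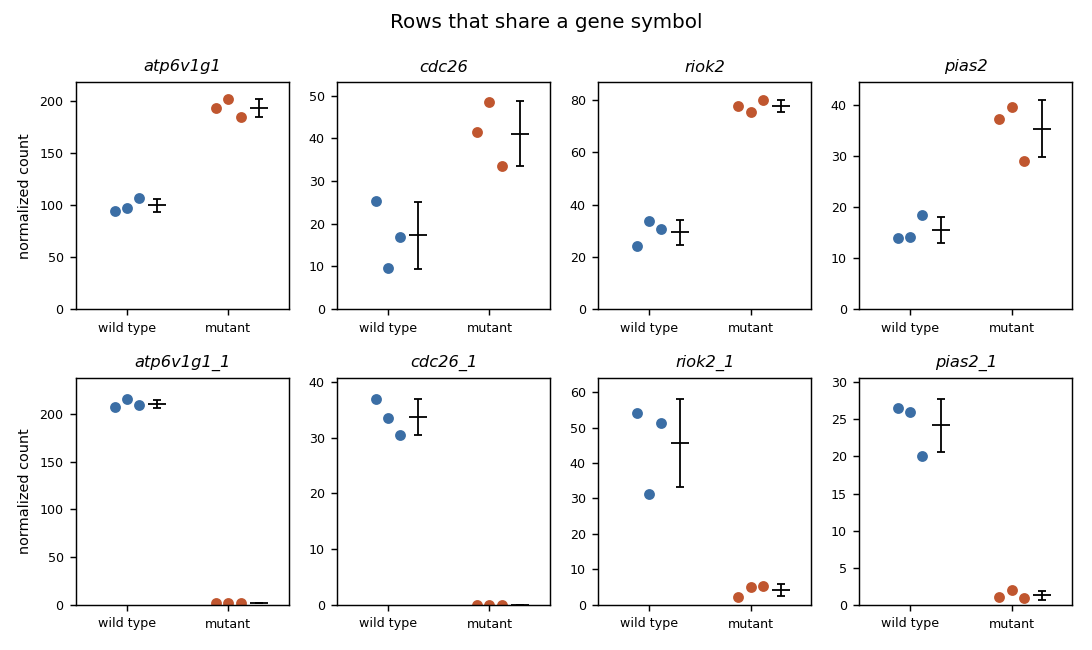
Normalized counts (y axis, linear, from 0) of 4 genes, 3 of them chosen after their values were seen, and of another row with the same symbol, in the 3 wild type and 3 mutant libraries; each point is a library and the black marks are the mean ± SD. The rows atp6v1g1_1 and cdc26_1 are near 0 in the mutants, at 1.97 and 0, while atp6v1g1 and cdc26 are higher there, at 193.5 and 41.1.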

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

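The alternatives were planned, except for the added one without suffixed names, which was chosen after the result was seen. With equal totals 1306 genes were lower. Without the trend 1007 genes passed (578 higher, 429 lower), of which 908 were among the 1873, and DESeq2 on the recovered counts called 1031 (622 and 409), all among the 1873, with 377 adjusted p values not given; the cause was not tested. A threshold of 1 on the log2 scale left 697 (431 and 266), as a stricter criterion must. edgeR called 1879, and none of the genes shared between any of the 18 refits and the 1873 changed direction. Leaving out 1 library gave 1419 to 1619 genes (778 to 983 higher, 586 to 661 lower) and 14 to 18 lists. The added alternative, which also leaves out the members of the lens and retina and erythroid lists, called 1765 genes (1023 and 742). With the correlation estimated per list, camera called 0 lists at an adjusted p of 0.05 against 15 with the preset one. Of the lists, 10 were past an unadjusted p of 0.05, and the smallest adjusted p was 0.0532. For the Wnt and angiogenic lists this loss did not come from correlated members, since their estimated correlations lay below the preset one. fry, which compares a list with no other genes, called 13. Only numbers 1 and 3 are shared by both genotypes, and residuals of same-numbered libraries correlated at 0.04 and -0.01. On the second principal component (13.1% of the variance) the libraries numbered 1 lay together, at 24.0 and 21.9, and those numbered 3 among the others, which spanned -16.3 to -7.82. Nothing in the labels says that a number marks a shared clutch or day, so the libraries were not treated as pairs, and whether those numbered 1 share one stays open. The replicate block gives each number its own term, so only the libraries numbered 1 and 3 inform its genotype difference. A library whose number occurs in 1 genotype only adds nothing to it. This setting is therefore not a refit of the whole comparison, and its counts rest on fewer libraries. In it 1597 genes (898 and 699) and 19 lists passed, among them the radial glia, myeloid, inflammatory and muscle lists, and scarb2a was at -0.19. The scarb2a difference lay between -0.01 and 0.88 over the libraries left out, and between -0.19 and 0.88 over all settings; it has no value with a mean of at least 20. No called gene or list that the text names changed direction in any alternative. Of 136 named genes that passed, 97 kept their call in every alternative that tested them. Most were named for a large change or a small p in these data, so this share does not stand for all 1873 calls. Most calls of the other 39 were lost in limma without a trend. Depth limits low genes: 1571 genes with a mean under 5 were not tested, scarb2a among them.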

Other observations

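Apart from the limma test of single genes and the setting with equal totals, which were planned, the tests in this part were chosen after the result was seen, as were the genes it names except cyp51. Genes were also grouped by the letters that open their symbols, into 134 families with at least 8 genes tested, and 13 families passed limma's camera at the preset correlation; none did with an estimated one (smallest adjusted p = 0.413). Keratin genes rose in 9 of 11 cases (median 1.21, camera adjusted p = 9.40e-09), minichromosome maintenance genes, the replicative helicase, in 7 of 10 (median 0.77, 2.61e-05), and annexin genes in 6 of 8 (median 0.82, 7.31e-05). All 16 crygm crystallin genes tested fell. Members of these families are also in the fixed skin, proliferation and lens lists, so the families are not independent support for those lists. Iroquois homeobox genes fell in 5 of 10 cases (median -0.36, 0.0131).

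gh1, the growth hormone gene of the pituitary, was among the more abundant transcripts and rose with little spread, from 3164 ± 53.7 to 6515 ± 165 normalized counts (SD, n = 3; limma adjusted p = 2.33e-10), higher in 3 of 3 mutants. The mitochondrial ribosomal RNA row mt-rnr1 rose by 0.94 on the log2 scale and mt-rnr2 by 0.35.

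Of 290 pairs of rows that share a gene symbol, 18 moved apart between genotypes (limma on the difference of log2 values, adjusted p under 0.05), in 9 pairs both rows passed in opposite directions, and for 8 of the 18 the sum of both rows had an unadjusted p of 0.05 or more. riok2_1 held 60.8% of its pair's counts in wild type and 5.10% in mutants, with sums of 75.1 and 81.7, while both rows of crx fell, with sums of 492.0 and 142.9. Of the 18 pairs, 13 lay on the chromosome that carries scarb2a in the assembly GRCz12tu, against 9 of the other 270 pairs placed (Fisher's exact test, two-sided, p = 3.19e-13). A candidate explanation for the moves apart, not for changes of the sums, is that the mutants are uniform for a stretch of chromosome linked to scarb2a, whose sequence matches only 1 of the copies of these genes in the reference, while the wild type pools hold more than 1 version; no sequence was examined. That most called genes are themselves linked to scarb2a is argued against. That chromosome held 6.05% of the genes past the threshold that could be placed (109 against 1692 elsewhere, with 415 tested genes not placed). Of its genes 22.2% passed, against 19.4% elsewhere (Fisher's exact test, p = 0.129). A linked variant that changes genes on other chromosomes would not show in these counts, so it stays open.

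The loss of lens transcripts is not matched by the retina. Less of every eye tissue in the mutant pools, by 1 factor, would lower retinal genes as far as lens genes if both came from the eye alone. The retinal median lay 3.12 above the upper quartile of the lens genes on the log2 scale. For the lens genes, near 0 in the mutants, the log2(value + 1) scale understates the fall and so narrows this gap. The whole lens and retina list took 0.327 to 0.451% of the counts in wild type and 0.0719 to 0.0895% in mutants. Lens genes held at most 0.00675% in any mutant, so most of what was left was retinal. These values argue against a loss of both by 1 factor, if the retinal markers come from the eye alone. Whether they do was not examined, and to that extent a common loss of eye tissue stays open. Lens cells or loose lens RNA sorted with the wild type pools only remain a candidate: the lowest wild type share of lens counts was 29.3 times the highest mutant share, and neither the sort for the reporter nor these libraries show whether lens cells pass the gate. This and a lens change in the mutants cannot be told apart, since each wild type library has more lens counts than any mutant library. The genotype itself stays open, as untested.

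The rise of cholesterol synthesis genes is not set by the scaling of the libraries: with equal totals the list's median was still 1.16, far beyond the shift of 0.11 in all genes. More mesenchymal and skin cells in the mutant pools stay open. The list's median lay 0.16 above that of 75 matrix, mural and epidermal genes (1.28 against 1.12, permutation test, one-sided, p = 0.112). Among its 21 genes only cyp51 lay above the highest of those markers (2.69). The permutation shuffled genes and not libraries, so its p does not measure variation between pools. How far added cells would move sterol genes beside their own markers was not measured, so the comparison cannot decide. A larger share of such cells may be part of the rise. An effect of the genotype within the sorted cells was not tested apart from cell composition, and heat shock and immediate early genes moved with the same libraries.

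For 3 libraries against 3, only 10 splits exist, so that no split test can reach a share under 0.05. For genes, 1 of the 10 splits called as many as the real 1873, the real one itself, and the highest other called 0. For gene lists, 2 of the 10 splits gave 15 or more lists, the real one included, and the highest other gave 16. In the other splits camera with a preset correlation called 8 to 16 lists. Those splits mix the genotypes, so part of the genotype difference stays in their spread and in their contrast. Their counts of genes and lists therefore give no rate of false calls.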
